A study of Arabidopsis thaliana with 6 samples.

How the data were processed

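RNA was measured in 6 libraries of Arabidopsis thaliana seedlings kept in darkness for 6 days, 3 of the wild type (Col-0, written wt) and 3 of lon1-1, a mutant of the gene for the mitochondrial protease LON1. Per the labels, total RNA had its ribosomal RNA removed, the libraries kept strand information, and DNA was digested on the extraction column. Genotype was taken from the sample titles, which name 3 wt and 3 lon1-1 libraries with replicate letters A, B and C. The genotype field of the labels reads Col-0 for all 6 libraries, so that field and the titles disagree for the 3 lon1-1 libraries, and the level of LON1 in each library is given with the results.

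The deposited table holds FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of each library), computed by the authors for each gene and library and written to 2 decimals. HISAT2, Bowtie2 and RSEM and the TAIR10 build are named in the submitters' notes without versions or order of use. The table lists 24193 genes. Of these, 24152 carry NCBI gene IDs, all 24152 of which were found in the TAIR10.1 annotation used for symbols, loci and chromosomes, and 41 are gene models added by the authors. The table lists 30 mitochondrial and 70 plastid genes, none of them coding for ribosomal or transfer RNA. The build behind the values and the annotation differ in name, so loci and chromosomes are given without positions.

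The table holds no fragment counts, so counts behind each value and intervals from counting are not given. Depth was estimated from the steps between low FPKM values of short transcripts, on a grid of 250000 fragments: it came to 33250000, 33000000 and 32750000 fragments in wt A, B and C and to 34500000, 34500000 and 35250000 in lon1-1 A, B and C. The estimate took 180 bases off each transcript length, an offset chosen from the values together with depth. At these depths and with that offset, 1 FPKM in a transcript of 1 kilobase stands for 26.9 to 28.9 fragments. Between 85.3% and 92.5% of the values used lay within 0.15 of a whole number of fragments. Depth and offset were chosen to bring values near whole numbers, so this share is no independent check.

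Because the values are FPKM, the comparison used limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes with a mean-variance trend) on log2(FPKM + 1), with genotype as the only term. Genes with at least 1 FPKM in at least 3 libraries were tested, and p was adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Log2 fold changes are lon1-1 minus wt and include the added 1, while ratios are of mean FPKM. The samples, the test and its form for FPKM, the gene lists, the rule for named genes and most alternative settings were chosen before the data were examined. The rule named LON1 and its 3 paralogs, the 8 genes with the largest rise and the 8 with the largest fall (past the threshold, mean of at least 5 FPKM, groups apart), and up to 4 changed members per list with the largest absolute change. Members named beyond that rule illustrate their list and were chosen after their values were seen.

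The 28 lists comprise 23 written from textbook knowledge and 5 taken from the annotation. They cover the Lon proteases, the mitochondrial dysfunction stimulon, alternative respiration, mitochondrial chaperones and proteases, the cytosolic heat shock response, the respiratory chain, nuclear photosynthesis genes, and dark growth regulators with chlorophyll synthesis. They also cover ethylene, auxin, brassinosteroid and gibberellin genes, cell wall expansion, the dark and sugar starvation response, seed oil breakdown, seed storage, root markers, shoot meristem and stomatal markers, and cell division. The rest are the low oxygen response, antioxidant enzymes, defence, flavonoid synthesis, the endoplasmic reticulum unfolded protein response, mitochondrial genes, plastid genes, cytosolic ribosomal proteins, pentatricopeptide repeat proteins and tau class glutathione transferases. Each list was tested with limma's camera against all other tested genes with a preset correlation of 0.01 between genes, again with the correlation estimated from the residuals, and with fry, with p adjusted over the lists. Gene Ontology terms of 10 to 500 tested genes were tested for genes higher and for genes lower by one-sided Fisher exact tests against all tested genes, with p adjusted over terms and directions. The share of summed FPKM from each organelle genome was compared by a two-sided exact permutation test, which cannot give a p under 0.1 with 3 libraries against 3. To compare classes of organelle products, FPKM was summed over the gene models of each product, the copies of mitochondrial genes on chromosome 2 and the added models included, because reads from the same sequence are divided among them.

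The limma test was tried on simulated data with the wt means of these libraries. Unlike the real data, spread was averaged over genes of similar level, genes varied independently, and equal numbers rose and fell. The counts below hold for that setting and may not carry over. With 200 genes changed 1.2-fold, 0 of the 193 tested were recovered. At 1.5-fold, 138 of 196 were recovered with 1 false call, and at 2-fold 177 of 196 with 1 false call. With 10000 genes changed 1.2-fold, 6282 of the 9741 tested were recovered, with 151 false calls among 6434.

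Alternative settings were a pseudocount of 0.1, no filter, leaving out organelle genes with the rest rescaled, a term for the replicate letter, and leaving out each library in turn. Median-ratio and upper-quartile scaling of FPKM, a filter at 5 FPKM, limma's treat against a fold of 1.5, shares weighted by transcript length, and shares that include added models and chromosome 2 copies were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.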

Results

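The data are gene expression values of whole Arabidopsis seedlings grown for 6 days in the dark, in 3 wt and 3 lon1-1 libraries. LON1 is an ATP-dependent protease of the mitochondrial matrix, and lon1-1 is a mutant of its gene. The FPKM of all listed genes summed to 724781, 719059 and 721823 in wt A, B and C and to 696877, 690404 and 696171 in lon1-1 A, B and C. Between 17861 and 18007 genes reached 1 FPKM in each library. Means are given in FPKM ± SD over 3 libraries per genotype (n = 3), and log2 fold changes as lon1-1 minus wt. Every gene said to have risen or fallen passed the limma threshold.

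The comparison asks how the transcripts of etiolated seedlings differ when LON1 is mutated. All tested members of the lists of nuclear photosynthesis genes (21) and of the starvation response (22) fell in lon1-1, and most members rose in the lists of mitochondrial chaperones and proteases (21 of 26), the respiratory chain (26 of 27), cytosolic ribosomal proteins (27 of 32) and seed oil breakdown (14 of 18). As lists, these passed limma's camera with the preset correlation, but in that order had adjusted p = 0.0677, 0.0625, 0.0625, 0.0677, 0.266 and 0.227 with an estimated correlation. Members that fell were 1 in the respiratory chain, 3 among ribosomal proteins and 3 in seed oil breakdown. LON1 itself (AT5G26860) had 4.69, 4.70 and 4.69 FPKM in the wt libraries and 2.67, 2.61 and 2.79 in the lon1-1 libraries, a log2 fold change of -0.63 (SE 0.055, adjusted p = 3.58e-06, limma). Against a fold of 1.5, chosen after seeing the data, limma's treat did not call LON1 (adjusted p = 1). That test used values with the added 1, which shrinks changes at low FPKM, while mean FPKM of LON1 fell 1.74-fold. LON2 (AT5G47040), the peroxisomal Lon protease, fell from 31.3 ± 1.2 to 19.9 ± 0.71 (SD, n = 3). The other paralogs were hardly detected in either genotype, with means of 0.0133 and 0.0133 for LON3 (AT3G05780) and of 0.0767 and 0.197 for LON4 (AT3G05790). The list of Lon proteases as a whole did not pass camera (2 tested, 2 lower, both also when adjusted over the list alone; adjusted p = 0.0656).

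Of 18308 genes tested, limma called 14104 changed at an adjusted p threshold of 0.05, 8182 higher and 5922 lower in lon1-1. Most changes were small: the median absolute log2 fold change of called genes was 0.44, and 746 genes rose and 872 fell at least 2-fold. Against a fold of 1.5, limma's treat called 2933 genes, 1525 higher and 1408 lower, and of the genes picked by the naming rule LON1 and 11 others, LON2, HSP90.1, STM and CDKB2;1 among them, did not pass. For genes at low FPKM this is partly due to the added 1: mean FPKM of STM, for example, fell 2.03-fold. With a pseudocount of 0.1, 1136 genes rose and 1247 fell at least 2-fold. With median-ratio scaling, chosen after seeing the data, 6985 genes rose and 7005 fell, and with upper-quartile scaling, chosen likewise, 7767 rose and 6345 fell. All lon1-1 libraries lay on one side of all wt libraries for 14483 genes (79.1%), where chance gives 10%.

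The largest rises were in a few nuclear genes and in organelle genes. MRD1 (AT1G53480) rose from 0.483 ± 0.0666 to 41.2 ± 2.09, QQS (AT3G30720), an orphan gene of carbon and nitrogen allocation, from 1.1 ± 0.0987 to 49.4 ± 3.77, and AT1G75945 from 0.290 ± 0.167 to 20.9 ± 1.45. The mitochondrial rpl16 gene rose from 76.0 ± 5.16 to 1197 ± 134. AT2G07734, on the chromosome 2 copy of mitochondrial DNA, and the plastid genes rps4 and rps15 were listed at 0 in each wt library. So was 1 of the 2 plastid rps12 models. Their lon1-1 means were, in that order, 240.5 ± 16.0, 55.5 ± 21.8, 31.5 ± 14.4 and 186 ± 7.57. The other rps12 model had 26.1 ± 0.0757 in wt and 27.1 ± 1.11 in lon1-1 and did not pass. Reads that match several gene models are divided among them, so a listed 0 does not show that no such transcript was present.

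The 8 largest falls included 3 nuclear photosystem genes. LHCB1.3 (CAB1, AT1G29930) and LHCB1.2 (CAB3, AT1G29910), light-harvesting proteins of photosystem II, fell from 1304 ± 37.1 to 37.5 ± 0.798 and from 47.5 ± 0.476 to 1.58 ± 0.28. AGT (AT2G13360), a photorespiratory aminotransferase, fell from 62.4 ± 1.67 to 3.09 ± 0.388. The carbonic anhydrase gene CA2 (AT5G14740) fell from 601 ± 16.1 to 40.8 ± 1.77, and PSAG (AT1G55670), a photosystem I subunit, from 155 ± 5.50 to 10.8 ± 0.865. AT4G33720 fell from 60.4 ± 4.06 to 0.663 ± 0.199 and AT4G37220 from 147 ± 1.73 to 4.44 ± 0.625. The added gene model BGI_novel_G000015 was also among the 8, at 64.8 ± 12.5 in wt and 0.78 ± 0.776 in lon1-1.

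Genes of the mitochondrial dysfunction stimulon, which the nucleus turns on when mitochondria are disturbed, were mostly higher. AT12CYS-2 (AT5G09570), a small cysteine-rich mitochondrial protein, rose 36.7-fold, from 0.403 ± 0.106 to 14.8 ± 0.664. SOT12 (AT2G03760), a sulfotransferase, rose from 9.89 ± 0.804 to 53.9 ± 2.21, and NAC013 (AT1G32870), a transcription factor of this response, from 5.44 ± 0.309 to 17.3 ± 0.477. OM66 (AT3G50930), an outer membrane protein of the same set, fell from 14.7 ± 0.781 to 11.2 ± 0.248. Of 15 tested members 12 rose and 1 fell, with the same counts adjusted over the list alone. The median log2 fold change was 1.53 (limma camera adjusted p = 0.000209; adjusted p = 0.0677 with an estimated correlation).

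Alternative respiration enzymes, which pass electrons around the proton-pumping complexes, rose in part. AOX1A (AT3G22370), the main alternative oxidase, rose 3-fold, from 17.3 ± 0.133 to 51.8 ± 1.64, and the external NADH dehydrogenase gene NDB4 (AT2G20800) rose from 0.207 ± 0.0153 to 4.14 ± 0.261. The uncoupling protein gene PUMP1 (AT3G54110) rose from 56.0 ± 0.73 to 115 ± 2.92. AOX1D (AT1G32350), another alternative oxidase, fell from 1.51 ± 0.04 to 0.253 ± 0.0404. Of 10 tested members 7 rose and 1 fell, also adjusted over the list alone (median 0.81, limma camera adjusted p = 0.0345; adjusted p = 0.195 with an estimated correlation).

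Mitochondrial chaperones and proteases rose in 21 of 26 tested members, and none fell, with the same counts adjusted over the list alone. MTHSC70-1 (AT4G37910), the matrix Hsp70, rose from 25.4 ± 0.679 to 73.7 ± 0.941, and the chaperonin gene HSP60 (AT3G23990) from 19.3 ± 0.897 to 52.7 ± 0.782. HSP60-2 (AT2G33210) rose from 6.44 ± 0.441 to 22.6 ± 0.452, and HSP23.5 (AT5G51440), a small mitochondrial heat shock protein, from 7.36 ± 1.41 to 31.3 ± 1.74. The matrix protease subunit CLPX2 (AT5G49840) had 11.8 ± 0.265 in wt and 11.1 ± 0.477 in lon1-1 and did not pass. The list median was 0.71 (limma camera adjusted p = 1.69e-05; adjusted p = 0.0625 with an estimated correlation). The cytosolic heat shock list had 1 member higher and 4 lower of 9 tested, also adjusted over the list alone, and did not pass camera (adjusted p = 0.0965, limma). There HSP90.1 (AT5G52640) rose from 8.38 ± 0.926 to 13.6 ± 0.202, while the heat shock factor HSFA7A (AT3G51910) fell from 14.4 ± 1.46 to 7.80 ± 0.419. All 6 endoplasmic reticulum unfolded protein genes rose, also adjusted over the list alone, with the lumenal chaperone gene BIP2 (AT5G42020) at 57.3 ± 1.90 and 152 ± 3.26. That list had a median of 0.89 (limma camera adjusted p = 0.0072; adjusted p = 0.117 with an estimated correlation).

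Nuclear genes for the respiratory chain rose in 26 of 27 members, and CAL2 (AT3G48680), a complex I subunit, fell from 77.4 ± 1.49 to 61.3 ± 2.66. The same counts held adjusted over the list alone. COX5B (AT3G15640), a cytochrome c oxidase subunit, rose from 58.5 ± 0.682 to 115 ± 1.58, and RISP1 (AT5G13430), the Rieske protein of complex III, from 75.3 ± 1.11 to 141 ± 0.275. CYTC-2 (AT4G10040), cytochrome c, rose from 12.1 ± 0.528 to 25.2 ± 2.46. The median was 0.49 (limma camera adjusted p = 4.87e-06; adjusted p = 0.0677 with an estimated correlation).

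All 21 nuclear photosynthesis genes fell, also adjusted over the list alone, with log2 fold changes from -5.08 to -0.71 and a median of -2.90. LHCB2.1 (AT2G05100), another light-harvesting protein, fell from 38.8 ± 2.63 to 2.38 ± 0.235, and LHCA2 (AT3G61470), an antenna protein of photosystem I, from 117 ± 1.34 to 9.03 ± 0.275. RBCS1A (AT1G67090), the small subunit of Rubisco, fell from 1492 ± 26.8 to 494.8 ± 10.8. Camera in limma gave an adjusted p of 9.96e-16 (adjusted p = 0.0677 with an estimated correlation). ELIP1 (AT3G22840) and ELIP2 (AT4G14690), light-induced thylakoid proteins examined after these values were seen, fell from 32.4 ± 1.97 to 14.9 ± 0.47 and from 26.2 ± 0.876 to 4.30 ± 0.566.

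Of 15 tested members of the list of dark growth regulators and chlorophyll synthesis, 4 rose and 10 fell, also adjusted over the list alone (median -0.29, limma camera adjusted p = 0.0411; adjusted p = 0.266 with an estimated correlation). GUN4 (AT3G59400) and CHLH (AT5G13630), both of the magnesium chelatase step, fell from 12.2 ± 0.595 to 3.07 ± 0.255 and from 26.4 ± 0.766 to 7.49 ± 0.13. PORA (AT5G54190) and PORB (AT4G27440), which reduce protochlorophyllide in light, fell from 181 ± 3.62 to 101.6 ± 0.29 and from 306 ± 6.63 to 138 ± 4.60. PIF4 (AT2G43010), a growth-promoting factor repressed by phytochrome, fell from 3.87 ± 0.622 to 1.48 ± 0.0551, while HY5 (AT5G11260), a promoter of greening, rose from 9.83 ± 0.927 to 18.9 ± 0.412. With median-ratio scaling, chosen after seeing the data, the list no longer passed (adjusted p = 0.0697).

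**Figure D1:**
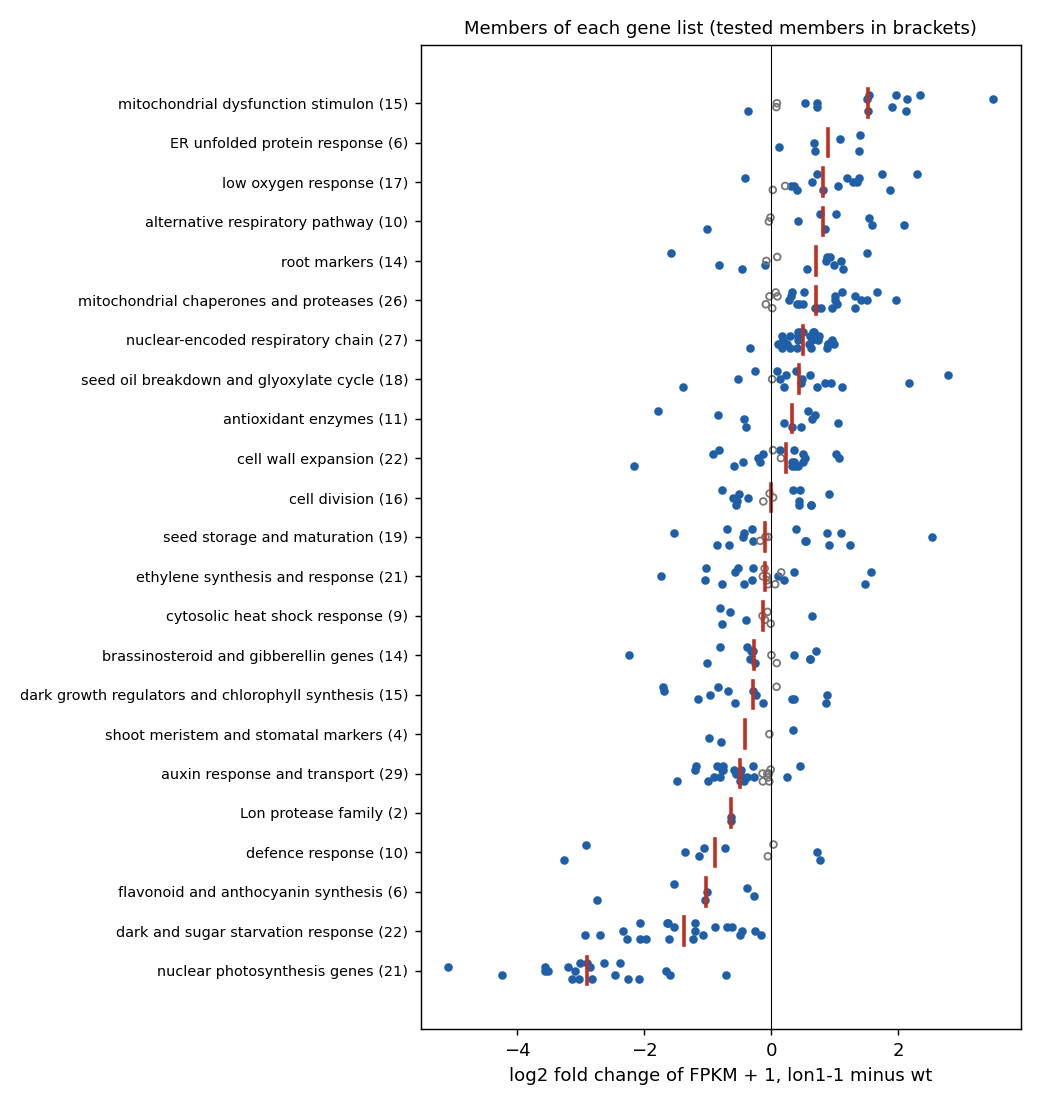
Log2 fold change of FPKM + 1 (lon1-1 minus wt, x axis) of each tested member of the gene lists on the y axis; filled points passed the limma threshold, open points did not, and red bars are list medians. Members of the photosynthesis and starvation lists all lie below 0, with medians of -2.90 and -1.37, while the mitochondrial dysfunction stimulon has a median of 1.53.

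Genes that darkness and sugar shortage normally raise were all lower in lon1-1. DIN2 (AT3G60140), a beta-glucosidase, fell from 77.5 ± 1.80 to 9.26 ± 0.119, and BCAT2 (AT1G10070) and DIN4 (AT3G13450), which break down branched-chain amino acids, fell from 52.1 ± 0.535 to 7.18 ± 0.488 and from 45.5 ± 1.09 to 8.23 ± 0.232. ASN1 (AT3G47340), an asparagine synthetase, fell from 290.5 ± 7.49 to 73.5 ± 0.69. All 22 members fell, also adjusted over the list alone, with a median of -1.37 (limma camera adjusted p = 3.81e-13; adjusted p = 0.0625 with an estimated correlation). Seed oil breakdown went the other way in most members. Both enzymes specific to the glyoxylate cycle rose, isocitrate lyase (ICL, AT3G21720) from 1296 ± 40.2 to 5864 ± 150 and malate synthase (MLS, AT5G03860) from 61.3 ± 1.19 to 430 ± 14.2. MFP2 (AT3G06860), of peroxisomal beta-oxidation, rose from 76.0 ± 1.22 to 167 ± 3.71, and PMDH2 (AT5G09660), a peroxisomal malate dehydrogenase, fell from 23.4 ± 0.495 to 8.33 ± 0.429. Of 18 members 14 rose and 3 fell, also adjusted over the list alone (median 0.43, limma camera adjusted p = 0.0133; adjusted p = 0.227 with an estimated correlation). Seed storage and maturation genes were split, 8 higher and 8 lower of 19 tested, also adjusted over the list alone (camera adjusted p = 0.713, limma). Within it ABI4 (AT2G40220), a transcription factor of abscisic acid and retrograde signalling, rose 25-fold, from 0.25 ± 0.0173 to 6.26 ± 0.325. CRA1 (AT5G44120), a seed storage globulin, rose from 25.2 ± 0.664 to 61.0 ± 2.77, while SESA1 (AT4G27140), a seed storage albumin, fell from 4.1 ± 0.364 to 0.77 ± 0.203.

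Auxin genes were lower in 20 of 29 members and higher in 2, also adjusted over the list alone. GH3.3 (AT2G23170) and GH3.2 (AT4G37390), which conjugate auxin to amino acids, fell from 50.9 ± 0.271 to 17.5 ± 0.871 and from 18.8 ± 0.295 to 7.74 ± 0.462. IAA29 (AT4G32280), a repressor of auxin response, fell from 10.7 ± 0.338 to 4.09 ± 0.247, and SAUR23 (AT5G18060), an auxin-induced growth gene, from 50.7 ± 2.43 to 24.9 ± 2.86. The median was -0.49 (limma camera adjusted p = 5.24e-06; adjusted p = 0.0625 with an estimated correlation). Ethylene genes had 5 higher and 9 lower of 21, brassinosteroid and gibberellin genes 4 higher and 8 lower of 14, and cell wall expansion genes 12 higher and 8 lower of 22, with the same counts adjusted over the list alone. None of these lists passed camera in limma (adjusted p = 0.106, 0.127 and 0.558). ACO1 (AT2G19590), of ethylene synthesis, rose from 21.4 ± 1.02 to 65.2 ± 2.30, while ACS6 (AT4G11280), the preceding enzyme, fell from 29.6 ± 0.712 to 8.18 ± 0.154. GASA6 (AT1G74670), a gibberellin-regulated gene, fell from 29.4 ± 0.578 to 5.48 ± 0.681, and CPD (AT5G05690), of brassinosteroid synthesis, from 88.4 ± 0.831 to 43.3 ± 1.77. The wall-loosening gene XTH24 (AT4G30270) fell from 930 ± 23.9 to 208 ± 5.40, and XTH19 (AT4G30290) rose from 215 ± 7.42 to 451 ± 5.81.

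Genes of the low oxygen response rose in 14 of 17 members and fell in 1, also adjusted over the list alone. HRE2 (AT2G47520), a low-oxygen transcription factor, rose from 3.70 ± 0.613 to 22.0 ± 1.36, SUS4 (AT3G43190), a sucrose synthase, from 48.5 ± 0.824 to 128 ± 1.26, and ADH1 (AT1G77120), alcohol dehydrogenase, from 173 ± 4.21 to 424 ± 27.4. The median was 0.82 (limma camera adjusted p = 0.000162; adjusted p = 0.0962 with an estimated correlation). The broader Gene Ontology term cellular response to hypoxia was enriched among genes that fell, with 132 of its 214 tested genes lower (one-sided Fisher exact test, adjusted p = 1.55e-16).

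Defence and flavonoid genes were mostly lower. CYP71A13 (AT2G30770) and CYP71A12 (AT2G30750), of camalexin synthesis, fell from 11.02 ± 0.245 to 0.257 ± 0.105 and from 34.1 ± 1.24 to 3.67 ± 0.245, while ICS1 (AT1G74710), of salicylic acid synthesis, rose from 4.02 ± 0.301 to 7.52 ± 0.242. Of 10 tested defence genes 2 rose and 6 fell, also adjusted over the list alone (median -0.89, limma camera adjusted p = 0.0207; adjusted p = 0.21 with an estimated correlation). Chalcone synthase (CHS, AT5G13930), which opens the flavonoid pathway, fell from 46.7 ± 0.38 to 6.16 ± 0.103. All 6 tested flavonoid genes fell, also adjusted over the list alone (median -1.02, limma camera adjusted p = 0.00352; adjusted p = 0.104 with an estimated correlation). Antioxidant enzymes were divided, 7 higher and 4 lower of 11, and tau class glutathione transferases had 14 higher and 5 lower of 24, with the same counts adjusted over the list alone. Neither passed camera in limma (adjusted p = 0.58 and 0.261). FSD1 (AT4G25100), an iron superoxide dismutase, fell from 593 ± 17.5 to 171 ± 6.43, while CSD1 (AT1G08830), a copper and zinc superoxide dismutase, rose from 289 ± 5.92 to 598 ± 23.4. GSTU18 (AT1G10360) fell from 3.13 ± 0.395 to 0.393 ± 0.0907, and GSTU8 (AT3G09270) rose from 17.7 ± 1.80 to 35.8 ± 0.412.

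Among root markers, 8 rose and 4 fell of 14 tested, also adjusted over the list alone (camera adjusted p = 0.31, limma). Those that rose were RHD6 (AT1G66470), a regulator of root hair formation, from 1.77 ± 0.312 to 6.90 ± 0.352, LRX1 (AT1G12040), of the root hair wall, from 7.44 ± 0.332 to 17.5 ± 2.60, RSL4, EXPA7, EXPA18, PRP3 and COBL9, which are known from root hairs, and GL2, a regulator of hairless root cells. Those that fell were the iron transporter gene IRT1 (AT4G19690), from 2.68 ± 0.256 to 0.237 ± 0.134, the endodermal gene CASP1 (AT2G36100), from 272 ± 13.1 to 153 ± 8.12, SHR (AT4G37650) and PHT1;1 (AT5G43350). The shoot meristem and stomatal markers had 1 higher and 2 lower of 4, also adjusted over the list alone (camera adjusted p = 0.414, limma). STM (AT1G62360), of the shoot meristem, fell from 4.73 ± 0.0971 to 2.33 ± 0.351, and TMM (AT1G80080), of stomata, from 4.73 ± 0.548 to 1.93 ± 0.401. Of 16 cell division genes 7 rose and 6 fell, also adjusted over the list alone (camera adjusted p = 0.784, limma). The 7 were PCNA1 and the 6 tested MCM genes of DNA replication, such as MCM2 (AT1G44900), from 2.95 ± 0.28 to 6.45 ± 0.702. The 6 were genes of mitosis and cytokinesis, such as CDKB2;1 (AT1G76540), from 18.3 ± 1.83 to 10.3 ± 1.23. The median of that list was 0.00 on the log2 scale and its camera direction was down.

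Cytosolic ribosomal protein genes rose in 27 of 32 tested members and fell in 3, also adjusted over the list alone. AT1G27400 rose from 34.2 ± 0.606 to 65.6 ± 2.47 and AT2G27710 from 52.5 ± 1.96 to 98.3 ± 3.11. The median was 0.44 (limma camera adjusted p = 0.000638; adjusted p = 0.266 with an estimated correlation). Genes for pentatricopeptide repeat proteins, which process organelle transcripts, had 94 higher and 34 lower of 204, and 90 and 31 adjusted over the list alone (camera adjusted p = 0.31, limma). Members were picked by words in their gene descriptions, and their place in the family was not checked further. The largest change in the list was in AT3G29240, which fell from 106 ± 1.09 to 19.1 ± 1, and PPR596 (AT1G80270) rose from 2.32 ± 0.154 to 6.16 ± 0.127.

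Mitochondrial genes made up 2.33% ± 0.0495 of summed FPKM in wt and 3.68% ± 0.163 in lon1-1 (SD, n = 3), and plastid genes 7.56% ± 0.0472 and 3.82% ± 0.137. Together they made up 9.89% ± 0.0172 and 7.50% ± 0.284. Each comparison gave an exact permutation p of 0.1, two-sided, the smallest that 3 against 3 allows. With added models and chromosome 2 copies counted, a choice made after seeing the data, the mitochondrial difference grew from 1.35 to 4.29 percentage points and the plastid difference went from -3.74 to -7.85.

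Of 27 tested mitochondrial genes 22 rose and 2 fell, also adjusted over the list alone (median 0.79, limma camera adjusted p = 7.59e-05, and adjusted p = 0.224 with an estimated correlation). Those that fell were atp8 and cob, the latter from 414 ± 58.5 to 225 ± 43.0. The ribosomal protein gene rps12 rose from 67.8 ± 5.77 to 510 ± 39.6 and shares its values with the chromosome 2 gene AT2G07675, and rpl2 rose from 58.1 ± 0.786 to 264 ± 4.54. Summed over gene models, all 7 mitochondrial ribosomal products were higher in every lon1-1 library, with a median log2 fold change of 2.17. Of 18 respiratory products 16 were higher in every lon1-1 library, with a median over the class of 0.56. Among the respiratory products atp8, an ATP synthase subunit, was lower in every lon1-1 library, at means of 3079 and 2284 FPKM, and atp4 overlapped between genotypes. The product cob, summed over 4 models, is among the 16 higher ones, at means of 1587 and 2602 FPKM. Its direction thus differed from that of the single cob gene.

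Of 69 tested plastid genes 27 rose and 34 fell, also adjusted over the list alone (median -0.23, limma camera adjusted p = 0.0345; adjusted p = 0.615 with an estimated correlation). That call ended without lon1-1 replicate A (median -0.12, adjusted p = 0.0556), without the filter (0.0571) and with median-ratio scaling, chosen after seeing the data (0.074). The 12 photosystem and Rubisco products were lower in every lon1-1 library, with a median of -1.80: psbA, of the photosystem II core, had means of 21490 and 6121 FPKM, and rbcL, the large subunit of Rubisco, 20870 and 6023. Of 23 ribosomal protein and RNA polymerase products 17 were higher in every lon1-1 library, 1 (rps14) was lower and 5 overlapped. The class median was 0.45. Among the 17 were rps4 and rps15, listed at 0 in wt, and rps12, of which 1 of 2 models was listed at 0 in wt. The polymerase gene rpoA had means of 139.8 and 246 FPKM. Plastid genes outside both classes went either way. For example, ndhH rose from 14.3 ± 6.14 to 105 ± 8.93, atpH fell from 3688 ± 74.1 to 1104 ± 36.7, and ndhA and atpF did not pass. The classes were compared by whether the genotypes overlapped, where chance puts them apart in 10% of cases. Of all tested genes, however, 79.1% were apart, so being apart does not by itself set a class off from other genes.

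**Figure D2:**
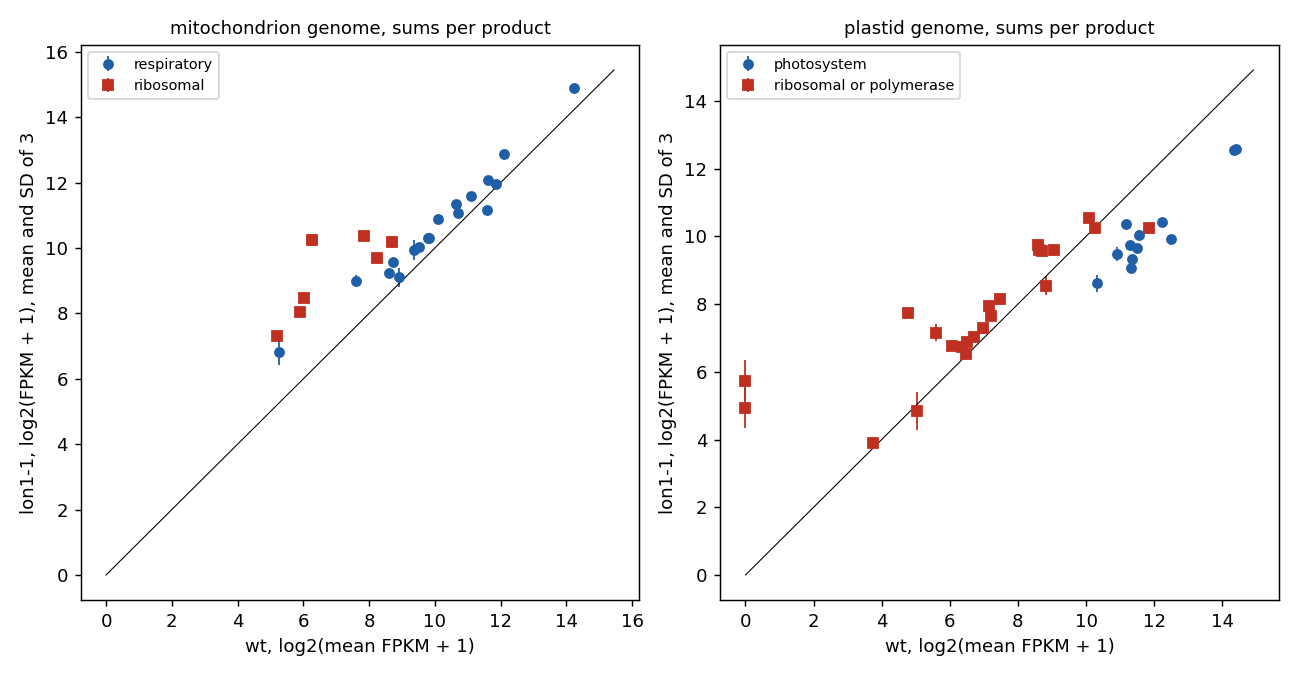
Organelle gene products, each summed over its gene models, in log2(FPKM + 1), with wt on the x axis and lon1-1 (mean, error bars SD, n = 3) on the y axis, for the mitochondrial (left) and plastid (right) genomes; the line marks equal values. Mitochondrial ribosomal products lie above the line with a median log2 fold change of 2.17 against 0.56 for respiratory ones, and plastid photosystem products below it with a median of -1.80 against 0.45 for ribosomal and polymerase ones.

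Among 1382 Gene Ontology terms, 165 were enriched in genes higher and 123 in genes lower in lon1-1; among genes changed at least 2-fold, 50 terms were enriched in those higher and 82 in those lower. The nucleolus (354 of 442 genes higher, adjusted p = 1.17e-50), structural constituents of the ribosome (316 of 386, 3.91e-49) and rRNA processing (91 of 111, 7.5e-14) were among those higher. The chloroplast thylakoid membrane (295 of 415 genes lower, adjusted p = 1.44e-56) and photosynthesis (84 of 111, 1.74e-18) stood out among the lower genes. These are one-sided Fisher exact tests in which genes, not seedlings, are the units, so correlated genes make the p values too small. No list that passed camera with the preset correlation, 16 in all, passed with an estimated one.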

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

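LON1 and the 118 other tested genes picked by the naming rule (LON3 and LON4 were below the filter) kept their direction and their side of the threshold under each alternative that tested them, except limma's treat against a fold of 1.5, chosen after seeing the data, where LON1 (-0.63) and 11 others no longer passed. Without 1 library at a time, limma called 13473 to 13696 genes (7783 to 8036 higher, 5607 to 5747 lower), with 730 to 755 higher and 858 to 896 lower at least 2-fold; LON1 ranged from -0.65 to -0.61, the mitochondrial share difference from 1.26 to 1.43, the plastid one from -3.82 to -3.69 and both together from -2.56 to -2.29 points. A term for the replicate letter as a block gave 14046 genes, 13877 of them shared, and changed no call on a list. Only 2 of 6 libraries were closest to their own letter, which gives no sign of pairing but, with 3 libraries per genotype, cannot exclude it. With a pseudocount of 0.1, 1136 genes were higher and 1247 lower at least 2-fold. Genes changed at least 2-fold gave 132 Gene Ontology terms (50 for higher genes, 82 for lower), 87 of them shared with the 288. Median-ratio scaling, chosen after seeing the data, gave 13990 genes but moved the share that were higher from 58% to 49.9%; it was 55% with upper-quartile scaling, also chosen then, and 57.2% with organelle genes left out.

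Also chosen after seeing the data were the treat test (2933 genes, 1525 higher, 1408 lower) and other ways to count shares. Weighting by transcript length gave differences of 0.93 (mitochondrial), -2.67 (plastid) and -1.75 (both); including added models and chromosome 2 copies gave 4.29, -7.85 and -3.56. For lists, fry called 11 more than camera. It tests each list by itself, not against other genes, and 77% of all tested genes were called, so these calls add no support. An estimated correlation ended all 16 calls, also for photosynthesis, where all 21 members fell (camera adjusted p = 0.0677, limma). That estimate rests on 3 libraries per genotype. The cytosolic heat shock list passed camera without the filter (adjusted p = 0.0361, limma). Dark growth (0.0697) and plastid genes (0.0556 to 0.074) lost their camera calls in the settings named with them, and the cause was not tested. The edgeR and DESeq2 alternatives need counts and were not run. Depth limits what can be said of genes near 1 FPKM.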

Other observations

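Gene Ontology terms outside the gene lists also moved in lon1-1. Among genes that rose, the proteasome complex had 58 of 69 tested genes (median log2 fold change 0.38, adjusted p = 1.49e-09), the trans-Golgi network 184 of 255 (0.34, 7.3e-17) and the tricarboxylic acid cycle 37 of 45 (0.38, 1.19e-05). The small-subunit processome, which assembles the small ribosomal subunit, had 38 of 41 (0.78, 8.97e-09). Among genes that fell, response to chitin, a fungal wall polymer, had 80 of 113 (-0.48, 9.32e-15), and water channel activity, the aquaporins, 20 of 25 (-0.82, 5.1e-05). Among genes that rose at least 2-fold, structural constituents of the cell wall had 15 of 24 (1.16, 2.11e-13) and glucosinolate synthesis 7 of 24 (0.24, 0.00135). The proteasome, trans-Golgi and tricarboxylic acid cycle terms did not pass among genes that rose at least 2-fold, while the processome, chitin and water channel terms passed in both sets, as did cell wall constituents; glucosinolate synthesis passed only in the 2-fold set. All are one-sided Fisher exact tests with p adjusted over terms and directions.

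The tests of light, of tissue proportions, of DNA carry-over and of plastid number that follow were chosen only after the result each one measures was seen. No biological explanation other than the genotype is given by the design, and an effect of the mutation stays open for each pattern as untested.

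The first pattern is the fall of all 21 nuclear photosynthesis genes. A larger root and smaller cotyledon portion in lon1-1 could lower them. Of 14 tested root markers 4 fell past the threshold while 8 rose, but 5922 of all 18308 tested genes fell too. With falls that common, those of root markers cannot decide, and tissue proportions stay open. Light reaching the wt seedlings stays open: PORA and PHYA, which light lowers, had log2 fold changes of -0.83 and -0.24 and go against it, while ELIP1 (-1.07) and ELIP2 (-2.36), which light raises, go with it. The criterion for light was made stricter after the ELIP values were seen, and by its first form, which read PORA and PHYA alone, light would have been excluded. A lower level of GLK1 and GLK2, activators of these genes, is also undecided, as their mean log2 fold change was -0.12, from -0.71 for GLK1 and 0.47 for GLK2.

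The second pattern is the larger rise of mitochondrial ribosomal products than of respiratory products. Reads split among overlapping gene models may distort single genes, and after summing models the class medians still differed by 1.61 on the log2 scale. Summing does not undo such splits, because the FPKM of each model is scaled by that model's own length. The rps4 sum, for example, includes AT2G07734, listed at 0 in each wt library and at a mean of 240.5 in lon1-1. Split reads therefore stay open for this pattern. DNA left in the preparations could add a like FPKM to every mitochondrial product, but no more than the level of the lowest one in lon1-1, nad3, which reached 147 in its highest library. The ribosomal products gained a median of 539 FPKM, and 6 of 7 gained more than that limit in every lon1-1 library over every wt library. The count was also 6 with rps7, the next lowest product (169), as the limit. Taken as they stand, these gains exceed what DNA alone would add. The sums cover unlike numbers of gene models, however, from 1 for rpl2 to 3 for rps12. Split reads can distort both the limit and the gains, so this comparison does not exclude DNA as the whole cause. This criterion replaced others set after the values were seen, which did not decide: 1 product (atp8) of 25 was lower in every lon1-1 library, and the gain of 12 of the 25 lay within a factor of 2 of the median gain.

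The third pattern is the fall of plastid photosystem products while ribosomal and polymerase products did not fall as a class. After summing gene models, the class medians still differed by 2.24. Summing cannot return reads placed outside the models of a product, and rps4 and rps15, with 1 model each, were listed at 0 in wt. Split reads therefore stay open here too. Fewer plastids per cell could lower all plastid products alike, yet the median log2 fold change of the ribosomal and polymerase class was at least 0.42 in each lon1-1 library. That value restates the pattern and shows only that a uniform fall is not the whole of it. A lower level of the sigma factors, which direct the plastid polymerase to photosystem genes, stays open: 2 of 6 fell (SIG1 and SIG4), SIG5 rose and the remaining 3 did not pass.

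The 6 libraries can be split into equal groups in 10 ways, which is too few for a share under 0.05. The real split gave 14104 genes, 16 gene lists and 288 Gene Ontology terms past the threshold, and the highest of the other splits gave 0 genes in limma, 12 lists and 0 terms. In each case 1 split, the real one, reached the real value. The other splits gave from 7 to 12 lists each, so lists passed camera with the preset correlation even where no gene passed. Every other split puts both genotypes in each group in unequal numbers. The genotype difference therefore enters its contrast as well as its spread. The counts of such a split are not those of libraries without a difference.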
